A study of Homo sapiens with 7 samples.

How the data were processed

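Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MCF-7, an oestrogen receptor-positive human breast cancer cell line. Per the labels' protocols, cells were held for 72 h in phenol red-free medium with 10% charcoal-stripped serum, which removes steroid hormones, and then given vehicle or, for 45 min, estradiol (E2) at 10 nM. Chromatin was crosslinked, released in a sarkosyl buffer, sonicated and made into libraries with a ThruPLEX kit, per the labels' protocols. The 7 samples are 1 menin library with vehicle, 1 menin library with E2, 1 MLL1 library and 1 MLL2 library with vehicle, and 3 inputs without antibody (2 with vehicle and 1 with E2). Peak lists of the 4 antibody libraries were analysed. The inputs were not analysed here, and which of them served as control for which list is not given in the sources used here.

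Each deposited list gives the start, the end, a peak name and a score for every peak. The submitters' processing notes name Bowtie, MACS2 and the genome build hg19, without versions or settings. The score is the authors' deposited value per peak. Its scale is not given in the sources used here. The lowest score was 2.02 with vehicle and 2.01 with E2 in the menin lists, 2.20 in the MLL2 list and 3.00 in the MLL1 list. The narrowest peak was 200 bp in both menin lists and in the MLL2 list and 135 bp in the MLL1 list, so the MLL1 list differs from the others in its lowest score and width, for reasons not given in the sources used here. Scores were used to rank or filter peaks within a list. Between lists only the lowest scores were compared, and 1 alternative applied a common lowest score of 3, which assumes a common scale that the sources used here do not give. The peak names carry 1 library name per file, so peaks were listed per library. Read depth is unknown, as the lists hold no read counts, and the number of peaks in a list depends on it.

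With 1 library per antibody and condition there are no replicates, and no test of a treatment or antibody effect was made. Lists were compared by overlap of at least 1 bp. Shares of peaks are given with exact Clopper-Pearson 95% intervals, which cover counting error over peaks only and not the difference between libraries. Neighbouring peaks are not independent, so these intervals are too narrow where peaks cluster. The overlap expected by position alone was taken from 1000 random placements of each list within its chromosomes, over the extent of each chromosome seen in the 4 lists. A second set of 1000 placements, chosen after seeing the data, moved all peaks of a chromosome by 1 common distance and so kept clusters together. Neither takes account of accessible or mappable sequence. Menin peaks of both conditions separated by gaps of up to 12.5 kb were joined into regions, a step chosen after seeing the data. Density ratios (peak centres per kb) are given with exact conditional binomial 95% intervals, and differences between clustered and single peaks with intervals from 1000 bootstrap resamples of whole clusters.

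Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The overlap code was checked against bedtools 2.31.1 and gave the same count in 24 of 24 comparisons. On simulated lists with 30% of the menin vehicle peaks planted, 30.2% were recovered. For the density ratio, independent counts of centres were drawn over the total length of the wide and the narrower menin vehicle peaks. With a ratio of 3, 94.5% of 200 intervals covered it, and with no difference 5% of 200 excluded a ratio of 1. The interval assumes such independent counts, so this checks the code only. Where several centres lie in 1 menin peak, the density intervals may be too narrow.

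The overlap definitions, the alternatives by score rank (upper 50% of each list) and by list length, and the rule for named peaks were fixed before the data were examined. The rule names the 8 highest-scoring peaks of each class: menin peaks found only with vehicle or only with E2, and menin vehicle peaks that overlap both MLL1 and MLL2 or neither. Further parts of the plan needed gene positions or sequence of hg19, which were not used here: the share of peaks near transcription start sites, by list and by MLL class, the peaks nearest to promoters and far from them, the promoters of the fixed gene lists, and consensus motifs under the peaks. A gene table of another build was at hand and was not joined to these coordinates, so peaks are named by position (hg19, 1-based) and not by gene.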

Results

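Menin, the scaffold protein encoded by the tumour suppressor gene MEN1, was mapped in MCF-7 breast cancer cells after hormone deprivation, with vehicle and after 45 min with 10 nM estradiol (E2). Its partners MLL1 and MLL2, histone methyltransferases that menin binds, were mapped with vehicle. The MLL2 antibody is labelled MLL2/TRX2. The menin list held 8516 peaks with vehicle and 6403 with E2, the MLL2 list 4998 and the MLL1 list 732. Each list comes from 1 library of unknown read depth, so differences between lists have no replicate check. Menin peaks had a median width of 346 bp with vehicle (quartiles 255 and 522 bp) and 336 bp with E2 (quartiles 253 and 495 bp), and the widest reached 9140 and 8899 bp. MLL2 peaks were of similar median width (357 bp) but never exceeded 1438 bp. MLL1 peaks were narrower, with a median of 186 bp and a maximum of 1028 bp, in a list with a higher lowest score than the others. Menin covered 4.16 Mb with vehicle and 3.02 Mb with E2, MLL2 covered 2.0 Mb and MLL1 0.161 Mb.

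The first comparison asked how the menin cistrome looked with and without E2. The strongest menin sites were present in both conditions, and 1 region on chromosome 2 stood apart. In the highest-scoring decile of the vehicle list 850 of 852 peaks (99.8%, 95% interval 99.15 to 99.97%) overlapped an E2 peak, and in the highest-scoring decile of the E2 list 640 of 641 overlapped a vehicle peak. At equal numbers of top-scoring peaks the overlap was 66.0% of vehicle peaks and 69.1% of E2 peaks. Over whole lists, which differ in length, 4860 vehicle peaks (57.1%, 56.0 to 58.1%) overlapped an E2 peak, and 4939 E2 peaks (77.1%, 76.1 to 78.2%) overlapped a vehicle peak. Random placement gave 0.226% and 0.293%. The lowest-scoring decile of the vehicle list overlapped the E2 list at 28.8% (25.8 to 32.0%) of its peaks, and the lowest-scoring decile of the E2 list overlapped the vehicle list at 58.0% (54.0 to 61.8%).

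**Figure D1:**
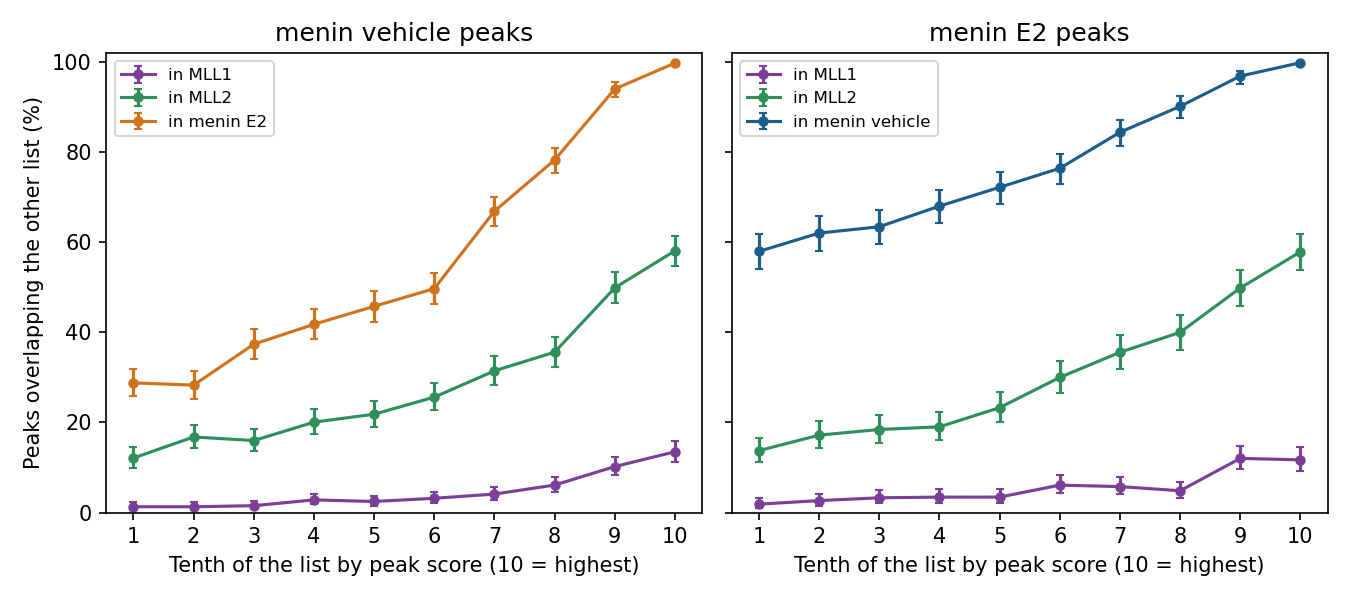
Share of menin peaks (percent, y axis) that overlap each other list, by decile of peak score within the list (x axis, 10 is the highest), for the vehicle list (left) and the E2 list (right), with 95% Clopper-Pearson bars. The overlap of the menin lists with each other goes from 28.8% to 99.8% of vehicle peaks and from 58.0% to 99.8% of E2 peaks between the lowest and the highest decile.

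Peaks found in a single condition were narrow and low in their own list. The 3656 vehicle-only peaks had a median width of 277 bp, against 425 bp for vehicle peaks shared with E2, and the 1464 E2-only peaks had a median width of 256 bp, against 371 bp for shared E2 peaks. The median score was 5.20 for vehicle-only and 9.82 for shared peaks within the vehicle list, and 5.03 for E2-only and 8.13 for shared peaks within the E2 list. Of the E2-only peaks, 40.3% lay within 1 kb of a vehicle peak, and 23.1% lay more than 100 kb from any. Of the vehicle-only peaks, 34.2% lay within 1 kb of an E2 peak and 28.3% more than 100 kb from any.

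The highest-scoring vehicle-only peak lay on chromosome 20 from 37075153 to 37075507 and overlapped an MLL2 peak, and the next lay on chromosome 19 from 45988592 to 45988880 and overlapped neither methyltransferase. The vehicle-only peaks ranked 3 to 8 lay on chromosome 12 (from 123849676), chromosome 11 (from 65913520), chromosome 7 (from 91763867 and from 106809029), chromosome 10 (from 102027308) and chromosome 9 (from 140099901). Of these, the peaks on chromosomes 12, 10 and 9 and the first of the peaks on chromosome 7 overlapped MLL2. The highest-scoring E2-only peak lay on chromosome 1 from 177540919 to 177541262, without MLL1 or MLL2. The E2-only peaks ranked 2 to 8 lay on chromosome 10 (from 112678858), chromosome 17 (from 56429462), chromosome 14 (from 21945160), chromosome 12 (from 116828238 and from 7047056), chromosome 8 (from 36919755) and chromosome 11 (from 30543257). Among them the peaks on chromosomes 10 and 14 and the second of those on chromosome 12 overlapped MLL2. None of these named peaks overlapped MLL1, while 61 of all 3656 vehicle-only peaks (1.67%) and 24 of all 1464 E2-only peaks (1.64%) did.

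Joined over gaps of up to 12.5 kb, the menin peaks of both conditions formed 5699 regions. Of these, 3641 (63.9%) held peaks of both conditions, 1453 vehicle peaks only and 605 E2 peaks only. The regions named next were chosen after their values were seen. On chromosome 2 from 11679641 to 11699568, 17 vehicle peaks covered 10.3 kb, and with E2 a single peak of 0.410 kb was listed, at the left end of the region (11679641 to 11680050). Neither MLL1 nor MLL2 had a peak there. E2 coverage was 0.0398 of vehicle coverage in this region, against 0.726 over all peaks. Among the 65 regions with at least 5 kb covered in either condition, the median ratio was 0.852 and the next lowest 0.228. That next region lay on chromosome 22 from 29190477 to 29219221, with 5.56 kb covered by 7 vehicle peaks and 1.27 kb by 5 E2 peaks. A region on chromosome 21 from 41685575 to 41713892 had 12 vehicle peaks over 5.76 kb and 4 E2 peaks over 1.70 kb, and another on chromosome 21 from 16424883 to 16439243 had 10 peaks over 5.73 kb and 6 peaks over 1.74 kb. The largest gain was on chromosome 4 from 134059345 to 134090774, where 14 vehicle peaks covered 6.88 kb and 15 E2 peaks covered 13.4 kb, a ratio of 1.94. The next highest ratio among the 65 regions was 1.21. Without replicates none of these differences was tested between conditions, and the vehicle and E2 labels could not be checked from these lists.

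**Figure D2:**
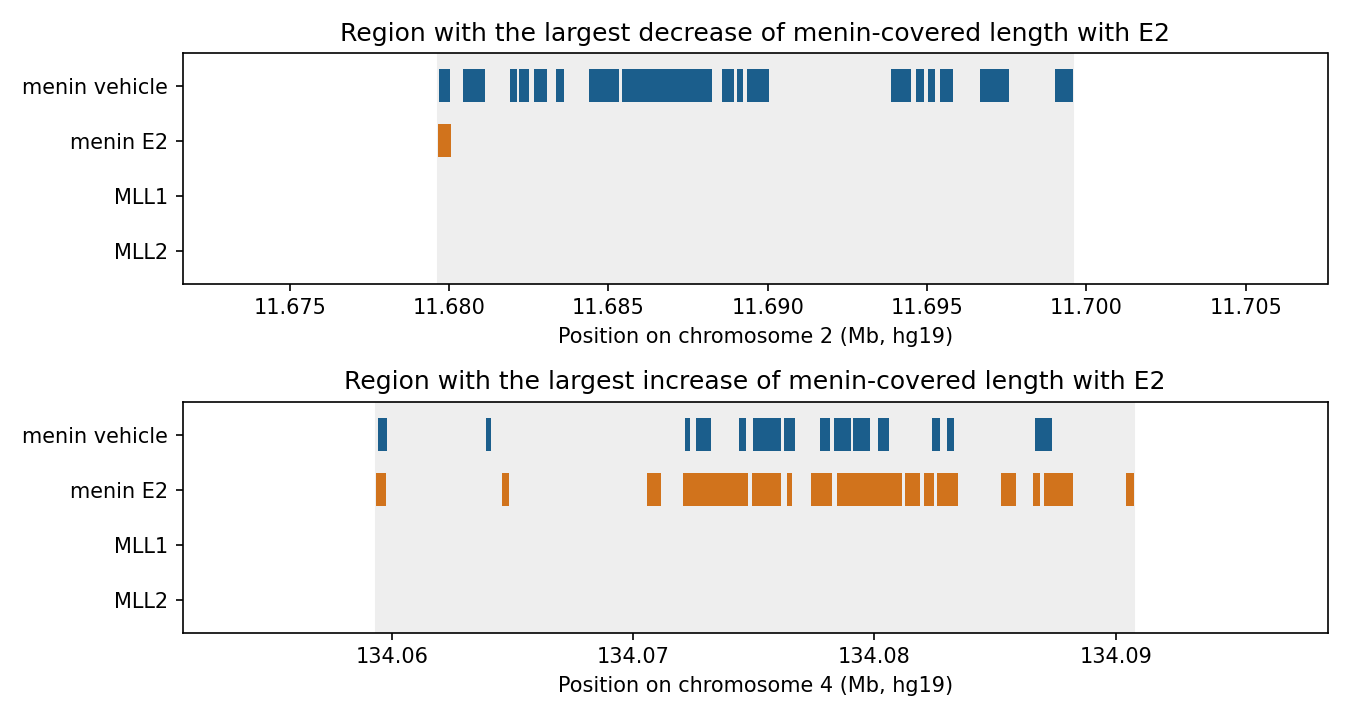
Peaks of the 4 lists (rows, 1 box per peak, drawn to scale) along chromosome 2 (upper map) and chromosome 4 (lower map), with the position in Mb (hg19) on the x axis and the joined region in grey. In the upper map 17 vehicle peaks stand over 1 E2 peak, and in the lower map 14 vehicle peaks stand over 15 E2 peaks; neither region has an MLL1 or MLL2 peak.

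The second comparison set menin against MLL1 and MLL2 in vehicle-treated cells. By an overlap of at least 1 bp, most MLL1 peaks lay on menin, and MLL2 peaks were divided nearly evenly between sites with and without a menin peak. Over the whole list most menin peaks overlapped no peak of either methyltransferase, but not among the highest-scoring ones. Of the MLL1 peaks, 454 of 732 (62.0%, 58.4 to 65.6%) overlapped a menin vehicle peak, against 0.244% after random placement. Of the MLL2 peaks, 2394 of 4998 (47.9%, 46.5 to 49.3%) did so, against 0.275%. This order depended on the definition, since with a reciprocal overlap of at least 50% of each peak the shares on menin were 9.97% for MLL1 and 31.4% for MLL2. In the highest-scoring decile of the MLL2 list the share was 79.0% (75.2 to 82.5%), and in that of the MLL1 list 87.8% (78.2 to 94.3%). Seen from menin, 2448 of 8516 vehicle peaks (28.7%, 27.8 to 29.7%) overlapped MLL2 and 396 (4.65%, 4.21 to 5.12%) overlapped MLL1. The second of these shares is bounded by the length of the MLL1 list. The MLL2 share was 12.1% (9.99 to 14.5%) in the lowest-scoring decile of the vehicle menin list and 58.1% (54.7 to 61.4%) in the highest-scoring decile. The menin peaks found with E2 overlapped the vehicle-treated MLL2 list at 30.5% (29.4 to 31.6%) and the MLL1 list at 5.51% (4.97 to 6.10%).

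**Figure D3:**
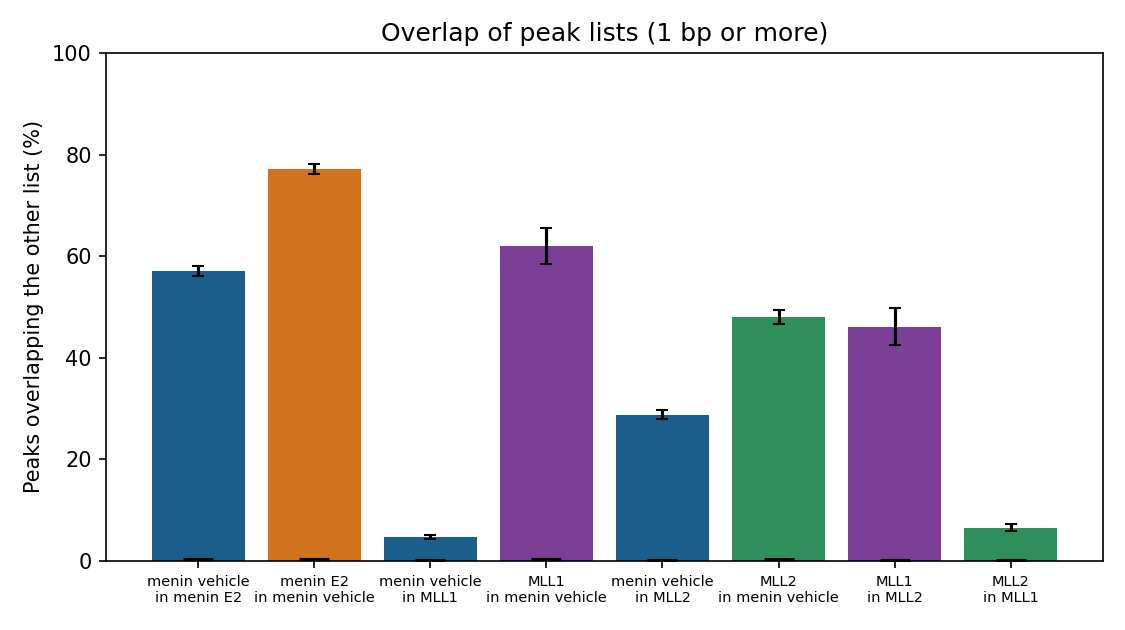
Share of the peaks of 1 list that overlap another list by at least 1 bp (percent, y axis; the x axis names the list and the list it is compared with), with 95% Clopper-Pearson bars; the black dashes near 0 are the means of 1000 random placements. The highest bars are E2 menin peaks in the vehicle menin list (77.1%) and MLL1 peaks in the vehicle menin list (62.0%).

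Menin vehicle peaks fell into 257 with both methyltransferases (3.02%), 139 with MLL1 alone (1.63%), 2191 with MLL2 alone (25.7%) and 5929 with neither (69.6%, 68.6 to 70.6%). The classes differed in width. Peaks with MLL1 alone had a median width of 866 bp and peaks with both 634 bp, against 381 bp with MLL2 alone and 325 bp with neither. They also differed in how often menin was found again with E2, which was 86.4% (81.6 to 90.3%) with both, 81.3% (73.8 to 87.4%) with MLL1 alone, 70.6% (68.6 to 72.5%) with MLL2 alone and 50.2% (49.0 to 51.5%) with neither. Median menin scores followed the same order of the classes, at 14.5, 12.4, 9.82 and 6.17. In the E2 list, menin peaks were also found with vehicle at 92.6% with both, 94.3% with MLL1 alone, 88.1% with MLL2 alone and 71.5% with neither. Vehicle peaks shared with E2 overlapped MLL2 at 36.4% (35.0 to 37.7%), vehicle-only peaks at 18.6% (17.4 to 19.9%) and E2-only peaks at 15.2% (13.4 to 17.1%). Shared peaks also had higher menin scores, and no comparison within menin score was made, so these differences are not separated from score. On chromosomes 1, 17 and 20, which carry amplified arms in MCF-7 cells, lay 26.1% (20.8 to 31.9%) of the menin peaks with both methyltransferases and 16.3% (15.4 to 17.3%) of those with neither.

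The highest-scoring menin peak of the vehicle list overlapped no peak of either methyltransferase. It lay on chromosome 12 from 6961354 to 6961915 with a score of 318, and the next peak with neither lay on chromosome 17 from 27279199 to 27279680 with a score of 290.3. The peaks of this class ranked 3 to 8 lay on chromosome 16 (from 30933686), chromosome 7 (from 63386266), chromosome 17 (from 21117203), chromosome 8 (from 67579365), chromosome 12 (from 54121163) and chromosome 1 (from 156736744). Among menin peaks with both MLL1 and MLL2 the highest-scoring lay on chromosome 1 from 151138250 to 151138784, with a score of 247, followed by chromosome 13 from 41706780 to 41707288, with a score of 208. Ranks 3 to 8 lay on chromosome 1 (from 114353101 and from 179851648), chromosome 17 (from 57181264 and from 57968800), chromosome 19 (from 52531510) and chromosome 3 (from 64008410). The first of the chromosome 17 peaks was 9140 bp wide, the widest menin peak of the vehicle list. All 16 of these menin peaks were found again with E2, as were 850 of the 852 peaks of the highest-scoring decile to which they belong.

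The third comparison set MLL1 against MLL2. Their overlap was higher where menin was present. Of the MLL1 peaks, 337 of 732 (46.0%, 42.4 to 49.7%) overlapped an MLL2 peak, against 0.114% after random placement, and 324 of 4998 MLL2 peaks (6.48%, 5.82 to 7.20%) overlapped an MLL1 peak. Among the 454 MLL1 peaks on menin, 55.7% (51.0 to 60.4%) overlapped MLL2, and among the 278 MLL1 peaks off menin 30.2% (24.9 to 36.0%) did. Among MLL2 peaks, MLL1 was found at 10.5% (9.32 to 11.8%) of those on menin and at 2.76% (2.17 to 3.47%) of those off menin. MLL2 peaks on menin were wider and higher in the MLL2 list than those off menin, with median widths of 417 and 305 bp and median scores of 12.5 and 8.26. MLL1 peaks on menin were also wider and higher in their list than those off menin, with median widths of 209 and 160 bp and median scores of 5.46 and 4.79. Whether width or score accounts for the higher overlap on menin was not tested. In all, 208 MLL1 peaks (28.4%) overlapped all 3 other lists, and 66 of these (31.7%, 25.5 to 38.5%) lay on chromosomes 1, 17 and 20, which held 20.9% of the whole MLL1 list. No other list was overlapped by 180 MLL1 peaks (24.6%) and by 2329 MLL2 peaks (46.6%). The MLL1 list is short and has a higher lowest score, so the absence of an MLL1 peak at a menin or MLL2 site does not show that MLL1 was absent there.

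The groupings by width and by cluster were chosen after the data were seen. Menin formed a minority of wide peaks, which overlapped MLL1 more often than narrower peaks did, although most of them overlapped no MLL1 peak. Of the 619 menin vehicle peaks of 1 kb or wider, 139 (22.5%, 95% interval 19.2 to 26.0%) overlapped MLL1, against 3.25% (2.87 to 3.67%) of narrower peaks, and at 2 kb or wider the share was 44.4% (36.3 to 52.7%). Of these 139 peaks 78 also overlapped MLL2, and 346 of the 619 overlapped neither methyltransferase. In all, 396 menin vehicle peaks of any width overlapped MLL1. The MLL2 share was 34.2% (30.5 to 38.1%) of the wide peaks and 28.3% (27.3 to 29.3%) of the narrower ones. In the E2 menin list these MLL2 shares were 31.7% and 30.4%, and per kb of vehicle menin peak MLL2 centres were 0.249 times (0.211 to 0.291) as frequent in wide as in narrower peaks. Of the 12 widest menin vehicle peaks, between 5.04 and 9.14 kb, 11 overlapped MLL1, 4 overlapped MLL2 and all 12 overlapped an E2 menin peak. All 12 belong to the highest-scoring decile of the vehicle list, in which 850 of 852 peaks overlapped an E2 menin peak. After the peak on chromosome 17 from 57181264 to 57190403, the widest lay on chromosome 14 (38055101 to 38064035), chromosome 13 (50646829 to 50655551) and chromosome 8 (116671809 to 116680191), each with MLL1 and without MLL2. The 1 wide peak of the 12 without MLL1 lay on chromosome 11 (65266362 to 65274069).

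**Figure D4:**
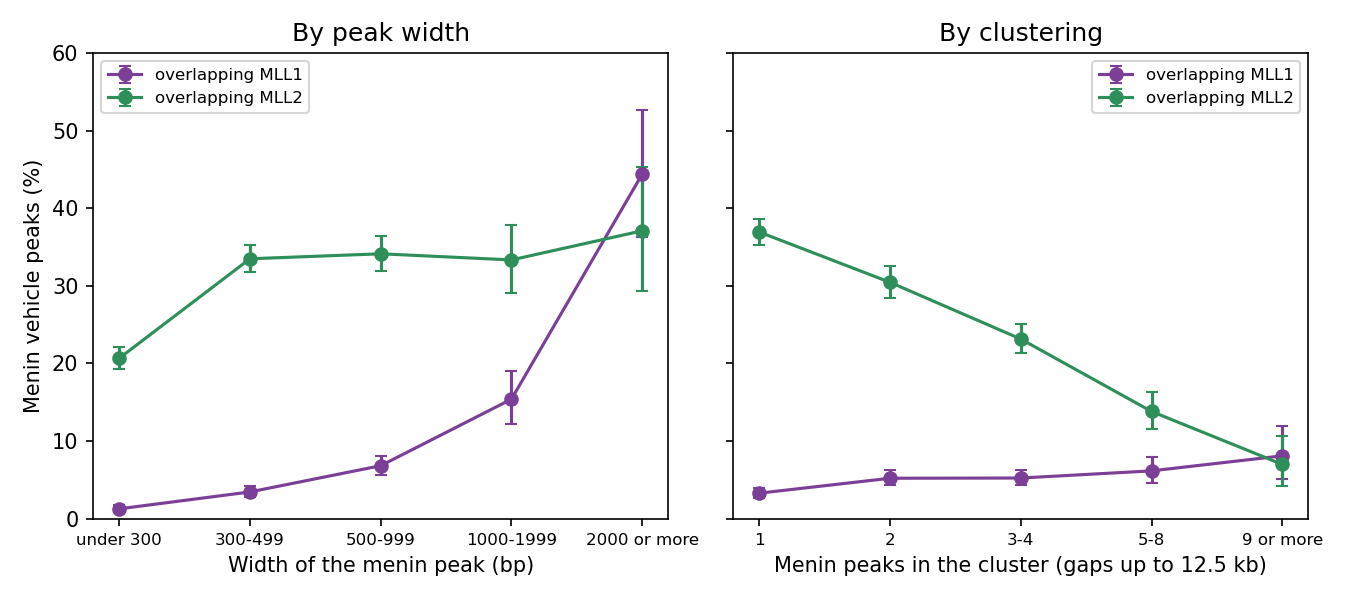
Share of menin vehicle peaks that overlap MLL1 or MLL2 (percent, y axis) by peak width in bp (left, x axis) and by the number of menin peaks in the cluster (right, x axis), with 95% Clopper-Pearson bars. The MLL1 share is 1.25% in the narrowest class and 44.4% at 2 kb or wider, and the MLL2 share is 36.9% of single peaks and 6.99% in clusters of 9 or more.

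Vehicle menin peaks also gathered in clusters. Joined over gaps of up to 12.5 kb they made 5104 clusters, of which 23 held 9 or more peaks. The largest lay on chromosome 6 from 26188777 to 26255271 with 21 peaks, 2 of them overlapping MLL1, none overlapping MLL2 and 15 found again with E2. On chromosome 10 from 8087633 to 8108383, 17 peaks covered 14.1 kb and all 17 were found again with E2, with 1 overlapping MLL2. The chromosome 2 cluster from 11679676 to 11699568 also held 17 peaks, and 1 of them was found again with E2. A cluster on chromosome 8 from 102501249 to 102525154 held 15 peaks over 13.5 kb, 12 of them found again with E2. MLL2 overlapped 36.9% (35.3 to 38.6%) of the 3296 single peaks and 12.2% (10.3 to 14.2%) of the 1134 peaks in clusters of 5 or more. MLL1 went the other way, at 3.28% (2.70 to 3.94%) of single peaks and 6.61% (5.24 to 8.22%) of peaks in these clusters. Clustered peaks were wider, with medians of 396 bp in clusters of 5 to 8 and 465 bp in clusters of 9 or more, against 317.5 bp for single peaks. The MLL1 difference was not adjusted for width, so it may not be separate from the width result. Of the 171 clusters of 5 or more, 100 (58.5%, 50.7 to 66.0%) held at least 1 peak with MLL2, against 56.0% for independent peaks with the same share per peak.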

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

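The score floor of 3, the placement that kept clusters together and every alternative of the results by width, cluster and region were chosen after seeing the data. No paired analysis was possible because each antibody and condition has 1 library, and for the same reason no replicate could be left out. Of 48 alternative values of the 8 overlap shares, 21 stayed within the 95% interval of the reported share and 27 did not, mostly because the definition of overlap or the length of the lists changed. In the order vehicle menin in E2 menin, E2 menin in vehicle menin, menin in MLL1, MLL1 in menin, menin in MLL2, MLL2 in menin, MLL1 in MLL2 and MLL2 in MLL1, a reciprocal overlap of at least 50% of each peak gave 40.9%, 54.4%, 0.857%, 9.97%, 18.4%, 31.4%, 12.6% and 1.84%. For MLL1 in menin, width limits this share: of the 454 MLL1 peaks on menin, 109 overlapped a menin peak at most 2 times as wide, as the definition requires. For MLL2 in menin width limits it little, since 2086 of 2394 MLL2 peaks on menin (87.1%) overlapped such a peak. For the other 6 shares the cause was not tested. Peak centres within 1 kb gave 67.2%, 83.5%, 6.92%, 67.6%, 38.7%, 56.8%, 56.7% and 8.44%. Equal numbers of top-scoring peaks gave 66.0%, 69.1%, 14.1%, 19.7%, 37.4%, 37.2%, 16.1% and 15.4%, where the menin list holds 732 peaks beside MLL1 and 4998 beside MLL2, so that these shares cannot be set against each other. Keeping the upper 50% of each list by score moved menin in MLL2 to 27.7%, MLL2 in menin to 46.1% and MLL1 in MLL2 to 41.8%, and left the other 5 shares within their intervals; the cause was not tested. Leaving out chromosomes 1, 17 and 20, or asking for scores of at least 3 in every list, moved none of the 8 beyond its interval. The alternatives for peaks near promoters, promoter share by MLL class, gene list promoters and motif share were not run, since those results need hg19 gene positions or sequence, not used here. Of 17 alternatives of the results by width, cluster and region, 0 reversed a direction, although those of the chromosome 2 region could not have done so. In the E2 list the MLL2 share of wide minus narrower menin peaks was 1.23 points, against 5.93 with vehicle. Random placement that kept clusters together gave 0.225% for vehicle menin in E2 menin and 0.233% for MLL1 in menin. Read depth, unknown here, limits every count of peaks missing from a list.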

Other observations

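The groupings by width, cluster and region used here, and the tests of room for an MLL1 peak and of MLL2 sites shared out over a cluster, were chosen after the results were seen. The 5-Mb bin with the most menin peaks in both conditions, chromosome 17 from 55 to 60 Mb, held 111 vehicle and 103 E2 menin peaks, 17 MLL1 peaks and 42 MLL2 peaks. MLL1 peaks were dense on chromosome 20 from 50 to 55 Mb, with 14 peaks, and on chromosome 3 from 60 to 65 Mb, with 13 peaks, and in each of these bins 10 of the MLL1 peaks overlapped no other list. Chromosomes 17 and 20 carry amplified arms in MCF-7 cells. Copy number was not examined in any of these bins, as the inputs were not analysed, so its part in these counts stays open.

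The menin peaks missing with E2 on chromosome 2 (11679641 to 11699568) were weighed against the lower peak yield of the E2 library. From the score decile and width class of its 17 vehicle peaks, 9.24 would be found with E2 at the rate seen over the whole list, and 1 was. The difference of -8.24 lies below that of each of the 168 other regions with at least 5 vehicle peaks, of which the lowest was -2.79. This rank adds no support, because the difference is a count that cannot fall below minus the number expected. A region on chromosome 8 (from 86376269) with 5 vehicle peaks, for example, had 3.87 expected and could not have reached -8.24. The region on chromosome 2 was also chosen as the one with the largest difference in covered length. Fewer of its peaks were found than the whole-list rate gives, but whether a general loss of yield is the whole cause was not decided. The direction held in the upper 50% of each list by score (-4.95 kb, against -9.90 kb in the whole lists), at equal numbers of peaks (-7.98 kb) and at scores of at least 3 (-9.34 kb) or 5 (-7.76 kb). With 17 vehicle peaks and 1 E2 peak listed there, these filters could not have reversed it, so they show its size and add no support. No biological explanation was tested, and a difference between these libraries other than the treatment stays open. An exchange of the vehicle and E2 labels also stays open, since no gene of known E2 response was placed on these coordinates and each condition has 1 library.

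Technical explanations were weighed for the MLL1 peaks at wide menin peaks. More room in wide peaks predicts equal MLL1 density, but MLL1 centres per kb were 2.18 times (1.79 to 2.65) as frequent in menin peaks of 1 kb or wider as in narrower ones, and 1.63 times (1.31 to 2.03) with each menin peak counted at most once. MLL2 centres per kb went the other way, at 0.249 times (0.211 to 0.291), although per peak MLL2 overlapped 34.2% of the wide and 28.3% of the narrower menin peaks. Without chromosomes 1, 17 and 20 the MLL1 ratio was 2.03 (1.60 to 2.55), which argues against amplification of those chromosomes as the whole cause. The MLL2 list cut to its 732 highest-scoring peaks gave 0.398 (0.302 to 0.518). This is below 1 but above the 0.249 of the whole MLL2 list, so the cut moved the ratio towards wide peaks. As MLL2 starts from another ratio, the cut cannot decide how much the short MLL1 list contributes. The strength of the menin peaks was not weighed. From the lowest to the highest score decile of the vehicle list, median width went from 269 to 501.5 bp. Between the same deciles the MLL1 share went from 1.29% to 13.5%, so a part of menin score in this pattern stays open. The calling of the MLL1 list and the efficiency of its antibody, not tested, stay open, and no biological explanation was tested.

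MLL2 was found less often at clustered menin peaks. It overlapped 12.2% (10.3 to 14.2%) of the 1134 peaks in clusters of 5 or more and 36.9% (35.3 to 38.6%) of the 3296 single peaks. The difference of -24.8 points (-27.4 to -22.1) was -21.2 points (-23.8 to -18.6) within deciles of menin score and -30.4 points (-33.4 to -27.3) within width classes, so weaker or wider peaks in clusters do not account for it. A single MLL2 site per locus, shared out over many menin peaks, was also weighed. In all, 128 different MLL2 peaks overlapped menin peaks of the 171 clusters, and 23 clusters overlapped 2 or more of them. Random assignment of these MLL2 peaks to the clusters by their number of menin peaks gave a mean of 29.9 such clusters, with 95% of 1000 assignments between 24 and 36. The count lies just below that range, in the direction that sharing out predicts. The margin is 1 cluster, the count of 23 was known before this test was chosen, and it was the last of 3 measures tried for this explanation; the others, set against single peaks, were decided by cluster size. Sharing out may therefore explain part of the lower share per peak, but the 23 clusters had more than 1 site, and how much it explains stays open. No biological explanation was tested.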
